A study of Mus musculus with 4 samples.

How the data were processed

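RNA was sequenced from Leydig cells isolated from the testes of male mice on a high-fat diet, in 2 WT and 2 C2orf74 KO libraries. RNA was extracted with Trizol and libraries were made by a standard Illumina protocol, per the labels' protocols. Groups were taken from the genotype in the labels, where replicate 1 and replicate 2 of each genotype are numbered in deposition order and were not treated as pairs in the main fit. The genome build mm9 is named per the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here.

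Each deposited file holds 1 value for each of 27357 Ensembl gene IDs, with no unit in its header. The deposited values were taken to be RPKM, reads scaled to gene length and library depth, which was inferred from the values themselves: multiplied by the summed exonic length of the gene in GENCODE release M21 they are whole multiples of 1 step per library. Between 90.4% and 90.7% of the values above 0 came out whole within 0.01 reads, and between 93.3% and 93.7% of those below 200 reads, against 2% by chance. The steps give 13847807 and 15817093 reads in WT and 15694389 and 19764004 in KO; whether these are reads or read pairs is not stated. These lengths belong to an annotation of GRCm38 and not of mm9, so coordinates are given from GENCODE M21 on GRCm38. Of the IDs, 27306 matched a symbol and a length and 51 did not. At the deepest library 3 reads of a gene of 1 kilobase are a low value, so genes near 1 RPKM carry counting error beside the spread between libraries, and floors of 3 reads cover counting error only.

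Genes at 1 RPKM or more in at least 2 libraries were kept (12391). The values were taken as log2(RPKM + 1), which understates the change of low genes, and KO was compared with WT with limma 3.58.1 in R 4.3.3 (linear model with genotype alone, empirical Bayes with a trend, 2-sided, Benjamini-Hochberg FDR of 0.05). All log2 changes are on this scale. The fit had 2 residual and 3.08 prior degrees of freedom. Gene lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 29 of 34 lists with at least 5 tested members, with an estimated correlation and with fry as alternatives. Camera compares a list with the other genes. Fry asks whether its members move, on balance, one way. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. The tests, gene lists and alternatives were fixed before the data were examined, with a count model planned for counts and the limma model for normalized values; the latter applied.

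Genes were named by a rule. It took the targeted gene, 7 steroidogenic and Leydig genes, the genes of at least 2-fold change, a mean of at least 5 RPKM and complete separation of the groups, and for each list past an FDR of 0.05 the 4 members with the smallest p, with up to 2 for other lists. Of the genes so chosen 3 are not given in the text. Symbols of the Gm, Rik and LOC series were left out of the fold change part. Since 0 genes passed, that part was filled by the smallest p to 5 lower genes and to the only 3 higher genes that met its other conditions.

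The fit was tested on simulated data for KO against WT with 2 libraries each, over 12383 genes. Depths and mean levels were those of the real libraries. The spread of each gene was drawn from the fit, alike for both genotypes, with counting error on top. In 20 simulations the fit recovered 56.0% of 2-fold changes and 93.8% of 4-fold changes at an FDR of 0.05, and 5.51% of calls were false. Changes were set on the log2(RPKM + 1) scale, so for low genes they exceed the named fold in RPKM, which may make recovery there too high. The fitted spread already held counting error, which was then added again and may make it too low. Which of these prevails was not tested. The shared spread leaves out that the KO pair differed more than the WT pair (chi-square per gene on recovered reads 25.2 against 5.08). Camera called a 23-gene list shifted 1.5-fold in 20 of 20 simulations. The simulated genes varied independently, so correlation between the members of a list was not part of that test, and 2.25% of unshifted lists had p under 0.05.

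The alternatives were quantile normalization, a trimmed-mean rescaling, no filter, a filter at 5 RPKM, a pseudocount of 0.1, limma without trend, each library left out in turn, and a replicate block from a suffix of the sample labels. Chosen after the data were seen were voom on the recovered reads of genes that were whole in all libraries, and a loess correction of each library for GC content and exonic length. Identity of libraries was checked by a chi-square per gene on recovered reads, which was 5.08 for the WT pair, 25.2 for the KO pair and 15.04 to 24.95 across genotypes, so no library repeats another. On this measure the KO libraries differed from each other at least as much as from the WT libraries.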

Results

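Gene expression was measured by RNA sequencing in Leydig cells, the androgen-producing interstitial cells of the testis, isolated from male mice that carried a knockout of C2orf74 (KO) or were wild type (WT). The mice were placed on a high-fat diet at 8 weeks of age and kept on it for 12 weeks. Each genotype had 2 libraries, and the comparison of KO with WT is the one the design implies. By its title the series asks how C2orf74 shapes the exchange between germ cells and Leydig cells and, through it, white adipocytes. The WT libraries held 13847807 and 15817093 reads and the KO libraries 15694389 and 19764004, as recovered from the steps between the deposited values. Between 12133 and 12242 genes per library stood at 1 RPKM or more. The Pearson correlation of log2 values across 12391 genes was 0.989 between the WT libraries and 0.981 between the KO libraries, and it lay between 0.979 and 0.983 across genotypes. Genes are not independent replicates. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

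The targeted gene could not be used to check the labels at this depth. C2orf74 is annotated in the mouse as 1700093K21Rik (ENSMUSG00000020286), on the minus strand of chromosome 11, positions 23516203 to 23521155 in GRCm38. It was listed at 0 in WT replicate 1, KO replicate 1 and KO replicate 2, and at 0.126 RPKM, or 4 reads, in WT replicate 2. A count of 0 allowed levels up to 0.108, 0.095 and 0.076 RPKM in these 3 libraries, counting error only, which are of the size of the single value seen. Which part of the gene was removed is not stated in the labels. Among 13 tested genes starting within 1 Mb of it, the log2 change ranged from -0.21 for Cct4 to 0.24 for Usp34.

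Among genes of moderate or high level, the largest differences, none of which passed the test, were higher values in KO for 3 metabolic enzymes and lower values for Nqo1, Cyp1a1 and others. Bhmt, which remethylates homocysteine from betaine, had 7.65 ± 0.0557 RPKM in WT and 18.6 ± 3.95 in KO (SD, n = 2 each), a log2 change of 1.16 ± 0.15 (SE). Values given in pairs below are RPKM in WT and then in KO. Adh1, an alcohol and retinol dehydrogenase, had 64.0 ± 6.73 and 142 ± 44.1 RPKM. Sult1e1, the oestrogen sulfotransferase, had 22.9 ± 5.06 and 49.3 ± 15.2. In the other direction, Nqo1, a quinone reductase, had 89.6 ± 12.96 RPKM in WT and 32.7 ± 8.67 in KO (log2 change -1.44 ± 0.20). Cyp1a1, the aryl hydrocarbon receptor target, had 23.9 ± 4.49 and 6.48 ± 2.90 (log2 change -1.78 ± 0.29). The keratinocyte envelope gene Sprr1a had 105 ± 14.8 and 44.6 ± 18.6 RPKM. The small heat shock gene Hspb1 had 19.5 ± 4.88 and 8.78 ± 0.960. Rps27a-ps2 (22.1 ± 5.54 and 9.86 ± 3.22) is a pseudogene that can share reads with Rps27a, so its values are uncertain. Their limma adjusted p-values ran from 0.13 for Bhmt to 0.28 for Sult1e1. In each case both KO libraries lay on the same side of both WT libraries, which was a condition for choosing these genes. The groups were separated in this way for 5536 of the 12391 genes tested.

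Among 12391 genes tested with limma, 0 were higher and 0 lower in KO at an FDR of 0.05, and the smallest adjusted p was 0.124. At an unadjusted p under 0.05 there were 536 higher and 919 lower genes, against 620 in all by chance, and under quantile normalization 662 and 749. Voom on the recovered reads likewise called 0 genes at an FDR of 0.05, where its smallest adjusted p was 0.0510. It gave 646 higher and 899 lower genes at an unadjusted p under 0.05. In limma 57 higher and 35 lower genes at that p differed by at least 2-fold. Only 3 higher and 7 lower genes combined a change of at least 2-fold, a mean of at least 5 RPKM and complete separation of the groups, and of the 7 lower genes 5 are named above. The count depends on which libraries supply the spread: without KO replicate 1, 111 genes were higher and 195 lower at an FDR of 0.05, and without KO replicate 2, 57 and 82, in fits whose spread came from the WT pair.

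**Figure D1:**
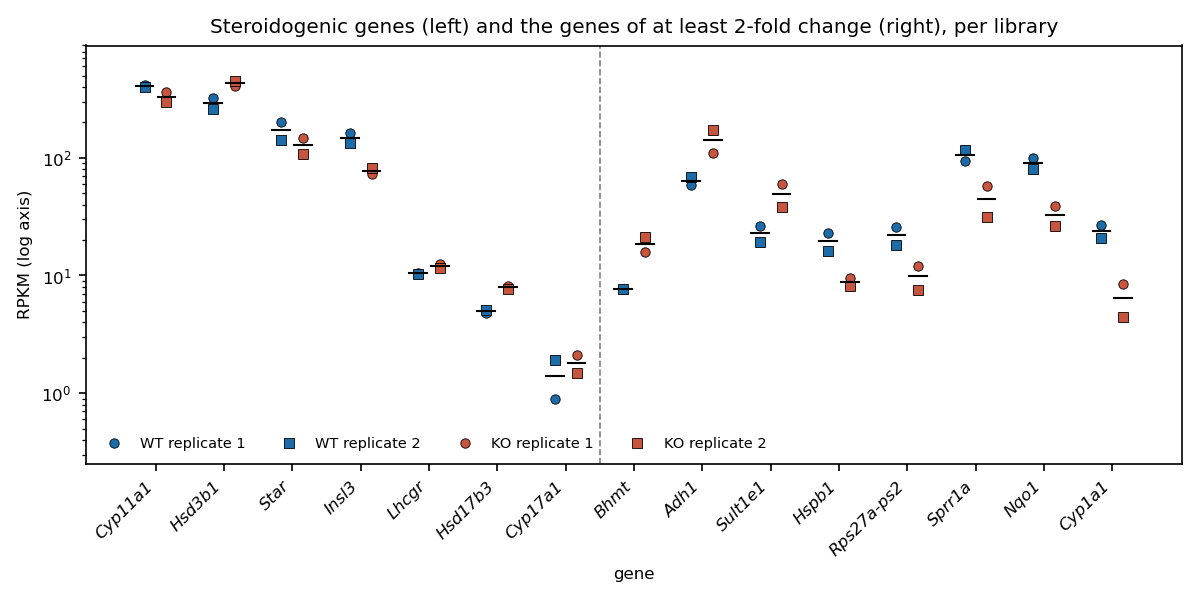
RPKM on a log axis for the 7 steroidogenic and Leydig genes (left of the dashed line) and the 8 named genes of at least 2-fold change (right), with WT libraries in blue, KO libraries in red, circles for replicate 1, squares for replicate 2 and a black line at each group mean. Insl3 lies at 164 and 133 RPKM in WT and at 73.0 and 81.5 in KO, and Nqo1 at 98.8 and 80.4 against 38.8 and 26.6.

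The steroidogenic genes lay on both sides of their WT values, and none passed the test. Insl3, the Leydig cell peptide hormone (chromosome 8, 71689214 to 71690575 in GRCm38), had 148 ± 21.9 RPKM in WT and 77.3 ± 6.02 in KO (SD, n = 2 each; log2 change -0.93 ± 0.13 SE, limma adjusted p = 0.154). Hsd17b3, which makes testosterone from androstenedione, had 4.98 ± 0.218 and 7.91 ± 0.280 RPKM (log2 change 0.57 ± 0.09, limma adjusted p = 0.161). The 3-beta-hydroxysteroid dehydrogenase Hsd3b1 had 292 ± 44.0 and 429 ± 27.1 (log2 change 0.56 ± 0.14, limma adjusted p = 0.295). Star, which carries cholesterol into mitochondria, had 171 ± 41.6 and 128 ± 28.7 RPKM. Cyp11a1, the side-chain cleavage enzyme, had 408 ± 9.38 and 330 ± 42.8. The luteinizing hormone receptor Lhcgr had 10.4 ± 0.173 and 11.9 ± 0.643 RPKM, and Cyp17a1 only 1.40 ± 0.705 and 1.79 ± 0.457. Of these 7 genes, 0 passed an FDR of 0.05 in limma or in voom on recovered reads. Insl3 (limma adjusted p 0.154 with all libraries) passed without KO replicate 1 (0.0447) and without KO replicate 2 (0.0418), in a range of 0.0418 to 0.688 over its alternatives.

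In the steroidogenesis list, 11 of 20 tested members were higher and 9 lower in KO, with a median log2 change of 0.07 (camera FDR = 0.222). Hsd3b6 had 472 ± 17.3 RPKM in WT and 747 ± 103 in KO. None of its members passed over all genes and 5 had an unadjusted p under 0.05; adjusted over the list alone, 4 were higher and 1 lower. The list of other Leydig cell genes rose relative to the remaining genes (13 of 20 members higher, median 0.12, camera FDR = 0.0110), a call that had an adjusted p = 0.43 with an estimated correlation and was lost without WT replicate 1 (FDR = 0.0927). The myoid, fibroblast, endothelial and macrophage lists, given below, moved the other way. The prolactin receptor Prlr had 73.6 ± 4.68 RPKM in WT and 113 ± 14.6 in KO. The peroxisomal oxidase Hao2 had 12.3 ± 0.665 and 21.2 ± 5.06, while Insl3, also in this list, lay lower. Adjusted over the list alone, 4 Leydig cell genes were higher and 1 lower, against 0 over all genes. Genes of luteinizing hormone and cAMP signalling did not pass as a list (median -0.03, camera FDR = 0.640). Akap12, a kinase anchor, had 28.9 ± 3.19 and 20.5 ± 2.36 RPKM. The adrenocortical list of 5 genes, for which the median (-0.22) and the test differed in sign, had a camera FDR of 0.787, and its member Mrap had 62.6 ± 4.05 and 76.1 ± 3.17 RPKM.

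Genes of cholesterol synthesis rose together in KO, while the myoid, fibroblast, endothelial and macrophage lists, given below, were lower. Of 23 tested members 22 were higher, with a median log2 change of 0.33 (camera FDR = 7.36e-11; adjusted p = 0.43 with an estimated correlation). The sterol carrier Stard4 had 13.7 ± 1.57 RPKM in WT and 21.9 ± 3.34 in KO (SD, n = 2 each), and the sterol reductase Tm7sf2 12.8 ± 1.38 and 18.7 ± 0.992. The farnesyl diphosphate synthase Fdps had 3.47 ± 0.444 and 5.89 ± 0.343. At an unadjusted p under 0.05 there were 12 members, of which 4 passed adjusted over the list alone and 0 over all genes. The size differed between the KO libraries, with a median of 0.17 in replicate 1 and 0.57 in replicate 2 relative to the WT mean.

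Fatty acid synthesis also rose as a list (17 of 21 members higher, median 0.23, camera FDR = 5.05e-05; adjusted p = 0.43 with an estimated correlation). Fasn, the fatty acid synthase, had 32.1 ± 4.46 RPKM in WT and 45.4 ± 5.50 in KO, the elongase Elovl5 160 ± 3.63 and 212 ± 6.73, and the phosphatidate phosphatase Lpin1 2.49 ± 0.309 and 3.61 ± 0.0210. The acyl-CoA ligase Acsl3 had 7.55 ± 0.0087 and 10.3 ± 1.05. Fatty acid oxidation rose by less (19 of 22 members higher, median 0.11, camera FDR = 0.000501; adjusted p = 0.43 with an estimated correlation). The lipid-sensing receptor Ppara had 3.04 ± 0.174 and 4.72 ± 0.142 RPKM, the dehydrogenase Etfdh 11.6 ± 0.0311 and 14.4 ± 0.412, and Acadm 42.6 ± 0.859 and 49.5 ± 1.86. Over all genes and adjusted over the list alone, 0 members of either list passed, with 7 and 4 members higher at an unadjusted p under 0.05. Lipid droplet and uptake genes did not pass (14 of 21 lower, median -0.09, camera FDR = 0.325). Adjusted over the list alone 2 were lower, Fabp5 (17.8 ± 1.20 and 11.9 ± 0.302 RPKM) and Hilpda (6.19 ± 0.409 and 4.14 ± 0.0516). White adipocyte genes (4 of 8 higher, camera FDR = 0.308) included Thrsp, at 1.42 ± 0.0461 and 3.56 ± 1.60 RPKM, and Acvr1c, at 0.655 ± 0.0257 and 1.22 ± 0.0892. Insulin and glucose genes (18 of 27 lower, camera FDR = 0.221) included the glucose transporter Slc2a1, at 15.2 ± 0.857 and 10.7 ± 0.163 RPKM, and hexokinase Hk2, at 41.2 ± 1.17 and 30.6 ± 1.59. The list passed as lower without KO replicate 2 (FDR = 0.0401).

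Immediate early and heat shock genes fell in KO. Of 28 tested members 26 were lower, with a median log2 change of -0.28 in each KO library (camera FDR = 1.69e-07; adjusted p = 0.43 with an estimated correlation). This was the one list that fry also called (FDR = 0.0297). Its genes were listed because they rise when tissue is dissociated, and no table separates the handling of the preparations from genotype. Gadd45b had 34.8 ± 0.360 RPKM in WT and 22.4 ± 0.854 in KO (SD, n = 2 each), and Ier3 142 ± 20.5 and 96.2 ± 10.2. The orphan receptor Nr4a1 had 5.57 ± 0.614 and 3.95 ± 0.0845. Hspb1 is given above. Adjusted over the list alone 2 members were lower, against 0 over all genes and 12 at an unadjusted p under 0.05. Unfolded protein response genes fell by less (20 of 26 lower, median -0.12, camera FDR = 0.00116; adjusted p = 0.43 with an estimated correlation). The endoplasmic reticulum chaperone Hspa5 had 332 ± 17.5 and 247 ± 4.35 RPKM, Hyou1 33.9 ± 0.0763 and 25.02 ± 0.305, and Creld2 44.3 ± 0.982 and 32.6 ± 1.05. Asparagine synthetase Asns had 19.5 ± 0.675 and 14.4 ± 1.57. Of this list 2 genes were lower adjusted over the list alone and 0 over all genes.

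The antioxidant list fell as well (20 of 30 lower, median -0.11, camera FDR = 0.00320; adjusted p = 0.52 with an estimated correlation), with its median at -0.06 in KO replicate 1 and -0.27 in KO replicate 2. Its call was lost without KO replicate 2 (FDR = 0.593). Thioredoxin reductase Txnrd1 had 71.1 ± 7.76 RPKM in WT and 36.9 ± 3.01 in KO, and sulfiredoxin Srxn1 70.7 ± 2.22 and 49.0 ± 0.846. Glutathione reductase Gsr had 25.2 ± 0.720 and 19.4 ± 0.343. Adjusted over the list alone 4 genes were lower and 0 over all genes. Secreted hormones and growth factors fell (30 of 39 lower, median -0.25, camera FDR = 9.34e-05; adjusted p = 0.43 with an estimated correlation). The myoid, fibroblast, endothelial and macrophage lists, given below, were lower alongside, and without the filter the median relative to all genes moved from -0.23 to -0.13. Beside Insl3, the platelet-derived growth factor Pdgfb had 6.95 ± 0.165 and 3.52 ± 0.345 RPKM, and Metrnl 13.6 ± 0.501 and 8.87 ± 0.358. The binding protein Igfbp3 had 2.97 ± 0.421 and 1.28 ± 0.0297. Adjusted over the list alone 9 of them were lower and 1 higher, against 0 over all genes.

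Inflammation genes fell (14 of 17 lower, median -0.29, camera FDR = 0.00320; adjusted p = 0.43 with an estimated correlation), a call lost without WT replicate 1 (FDR = 0.104) and at a filter of 5 RPKM (FDR = 0.0766). Relative to all genes the median moved from -0.28 to -0.12 without WT replicate 1, -0.14 without KO replicate 1 and -0.14 without the filter. Macrophage genes, given below, were lower alongside, and both lists lay lower in KO replicate 1 than in KO replicate 2. The chemokine Ccl2 had 35.7 ± 3.31 RPKM in WT and 20.3 ± 0.493 in KO and was the only member to pass adjusted over the list alone. Ccl4 had 5.15 ± 0.917 and 3.75 ± 0.116, and Tnf 2.34 ± 0.307 and 1.37 ± 0.1003. Il1rn had 2.33 ± 0.434 and 0.905 ± 0.336. The interferon list rose slightly (13 of 19 higher, median 0.09, camera FDR = 0.0247; adjusted p = 0.47 with an estimated correlation). It lost its call without WT replicate 2, without KO replicate 1 and at a filter of 5 RPKM (FDR = 0.0696). Relative to all genes the interferon median moved from 0.10 to 0.0085 without WT replicate 2, and to 0.21 with voom. The RNA sensors Ifih1 (2.61 ± 0.181 and 3.45 ± 0.0708 RPKM) and Ddx58 (4.32 ± 0.162 and 5.03 ± 0.174), Stat2 (10.03 ± 0.0326 and 11.7 ± 0.346) and the GTPase Iigp1 (12.3 ± 2.23 and 17.2 ± 3.73) had the smallest p-values of the list. Over all genes 0 passed, and 0 passed adjusted over the list alone. Retinoid genes did not pass (median 0.12, mean -0.02, camera FDR = 0.640), with the retinal dehydrogenase Aldh1a3 at 3.34 ± 0.347 and 1.32 ± 0.474 RPKM and Dhrs3 at 55.2 ± 3.40 and 70.7 ± 16.02.

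Markers of several other cells of the testis were lower in KO. The list of peritubular myoid and smooth muscle genes fell (11 of 14 lower, median log2 change -0.29, camera FDR = 0.000276; adjusted p = 0.47 with an estimated correlation). Des, the muscle filament gene, had 5.87 ± 0.172 RPKM in WT and 3.02 ± 0.0511 in KO (SD, n = 2 each), the pericyte gene Rgs5 5.55 ± 1.87 and 2.30 ± 0.416, and Mcam 2.11 ± 0.271 and 1.02 ± 0.166. Smooth muscle myosin Myh11 had 2.69 ± 0.294 and 1.68 ± 0.0440; adjusted over the list alone 6 genes were lower and 0 over all genes. Fibroblast and matrix genes fell (22 of 28 lower, median -0.26, camera FDR = 0.000299; adjusted p = 0.43 with an estimated correlation). The collagen genes Col1a1 (111 ± 15.03 and 76.6 ± 9.52 RPKM) and Col5a2 (37.8 ± 0.769 and 29.3 ± 3.14) were among them, as were Timp3 (35.9 ± 1.05 and 28.2 ± 2.21) and Mfap5 (2.44 ± 0.263 and 1.11 ± 0.0683). Of its members 0 passed adjusted over the list alone or over all genes.

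Endothelial genes fell (6 of 8 lower, median -0.56, camera FDR = 0.00320; adjusted p = 0.43 with an estimated correlation), and lost the call without WT replicate 1 (FDR = 0.0936) and without WT replicate 2 (FDR = 0.290). The median was -0.31 in KO replicate 1 and -0.69 in KO replicate 2. Relative to all genes it moved from -0.55 to -0.30 without KO replicate 2 and to -1.11 with voom on recovered reads. It was -0.54 without WT replicate 1 and -0.43 without WT replicate 2. Cldn5, Esam and Sox18 passed the filter only through the WT libraries. Cldn5, a junction gene, had 2.90 ± 0.706 RPKM in WT and 0.578 ± 0.498 in KO, Esam 2.22 ± 0.141 and 0.872 ± 0.0393, and Eng 10.8 ± 0.673 and 7.30 ± 0.870. Cdh5 had 13.4 ± 0.330 and 9.14 ± 3.09; 3 were lower adjusted over the list alone and 0 over all genes. The macrophage list fell on average (22 of 28 lower, median -0.25, camera FDR = 0.0133; adjusted p = 0.79 with an estimated correlation), but its median was -0.58 in KO replicate 1 and 0.05 in KO replicate 2. Its call was lost without WT replicate 1 (FDR = 0.600), and without KO replicate 1 its median relative to all genes was 0.07 (FDR = 0.414). Cd68 had 119 ± 19.3 and 82.2 ± 21.7 RPKM, Csf1r 25.1 ± 4.72 and 18.7 ± 3.55, and Cd14 24.2 ± 1.06 and 19.7 ± 0.502. Spi1 had 9.22 ± 0.458 and 6.30 ± 1.32, and 0 members passed adjusted over the list alone. Sertoli cell genes, with 10 of 27 listed genes tested, did not pass (6 of 10 lower, median -0.16, camera FDR = 0.450). Amhr2 had 51.1 ± 5.18 and 40.8 ± 1.47 RPKM and Inhbb 5.43 ± 0.331 and 3.48 ± 0.532.

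Germ cell genes stood near the filter of 1 RPKM. Only 6 of 47 listed spermatid genes were tested, and the list was called higher (5 of 6 higher, median 0.27, camera FDR = 0.0328; adjusted p = 0.43 with an estimated correlation). It lost its call without the filter (FDR = 0.173, median relative to all genes 0.013), and without WT replicate 1 (FDR = 0.0936), KO replicate 1 (FDR = 0.326) or KO replicate 2 (FDR = 0.133). Protamine Prm1 had 0.356 ± 0.0682 RPKM in WT and 1.15 ± 0.102 in KO, Dnajb3 0.971 ± 0.182 and 1.92 ± 0.540, and Gapdhs 1.97 ± 0.318 and 3.10 ± 0.702. Crem had 1.92 ± 0.0426 and 1.73 ± 0.0229. The spermatogonial list, with 5 of 18 listed genes tested, was called higher (4 of 5 higher, median 0.28, camera FDR = 0.0467; adjusted p = 0.43 with an estimated correlation). It lost its call without WT replicate 1 (FDR = 0.0800) or WT replicate 2 (FDR = 0.0506) and at a pseudocount of 0.1 (FDR = 0.0593), and its median relative to all genes was 0.022 without the filter. Kit, which Leydig cells also express, had 16.3 ± 0.376 and 22.5 ± 3.16 RPKM, Zbtb16 8.27 ± 0.893 and 10.3 ± 1.78, and Dazl 0.267 ± 0.0737 and 1.04 ± 0.0329. Uchl1 had 5.79 ± 0.362 and 4.93 ± 0.972. Both germ cell calls were also lost under quantile normalization and in voom on recovered reads. Prm1 and Dazl passed the filter only through the KO libraries, so neither call is taken as a rise. Adjusted over the list alone 0 spermatid and 2 spermatogonial genes were higher. Fewer than 5 members passed the filter for thermogenic adipocytes (3), spermatocytes (4), lymphocytes and other leukocytes (1), erythroid cells (3) and epididymal epithelium (1), which were not tested.

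Proliferation genes fell at low level (24 of 28 lower, median -0.15, camera FDR = 0.00168; adjusted p = 0.43 with an estimated correlation). Without WT replicate 2 the call was lost, and the median relative to all genes moved from -0.13 to -0.08. Ccnb2 had 4.99 ± 0.282 RPKM in WT and 3.37 ± 0.287 in KO, Cdc20 7.56 ± 1.08 and 5.17 ± 0.0786, and Plk1 3.36 ± 0.205 and 2.65 ± 0.223. Ube2c had 4.07 ± 0.773 and 3.06 ± 0.101, and 0 passed adjusted over the list alone. Cytosolic ribosome genes were called lower by little (64 of 77 lower, median -0.08, camera FDR = 0.0469; adjusted p = 0.80 with an estimated correlation). Without WT replicate 2 the FDR was 0.613, and without KO replicate 2 the median relative to all genes was 0.04 (FDR = 0.189). The call was also lost under quantile normalization (FDR = 0.292), at a filter of 5 RPKM (FDR = 0.186), with the replicate block (FDR = 0.0547) and after the GC and length correction (FDR = 0.214). Fau had 242 ± 17.7 and 213 ± 13.7 RPKM, and Rpl39 37.8 ± 2.12 and 32.2 ± 6.22. Rps23 had 206 ± 12.6 and 178 ± 28.5. Ribosomal protein genes can share reads with pseudogenes. Nuclear genes of oxidative phosphorylation did not pass (44 of 79 higher, median 0.01, camera FDR = 0.0834), with Ndufc2 at 48.5 ± 7.08 and 65.1 ± 0.230 RPKM and Uqcrfs1 at 74.1 ± 0.910 and 60.1 ± 4.29. That list passed as higher under quantile normalization (FDR = 0.00703), at a filter of 5 RPKM (FDR = 0.0467), after the GC and length correction (FDR = 0.0291) and without WT replicate 2 (FDR = 0.00181) or KO replicate 2 (FDR = 0.00115). Lysosome and autophagy genes did not pass (17 of 27 lower, camera FDR = 0.640), with Map1lc3a at 53.7 ± 0.276 and 41.3 ± 0.521 RPKM and Neu1 at 23.5 ± 0.747 and 29.4 ± 3.65. Mitochondrially encoded genes did not pass (8 of 12 higher, median 0.13, mean -0.13, camera FDR = 0.543), but adjusted over the list alone 4 were lower (mt-Co3, mt-Co2, mt-Atp6 and mt-Nd3) and 0 higher. The values of mt-Co3 (28.9 ± 0.818 and 15.4 ± 0.103 RPKM) and mt-Co2 (57.2 ± 4.61 and 35.8 ± 4.98) are uncertain, since mitochondrial genes can share reads with nuclear copies, which was not tested.

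**Figure D2:**
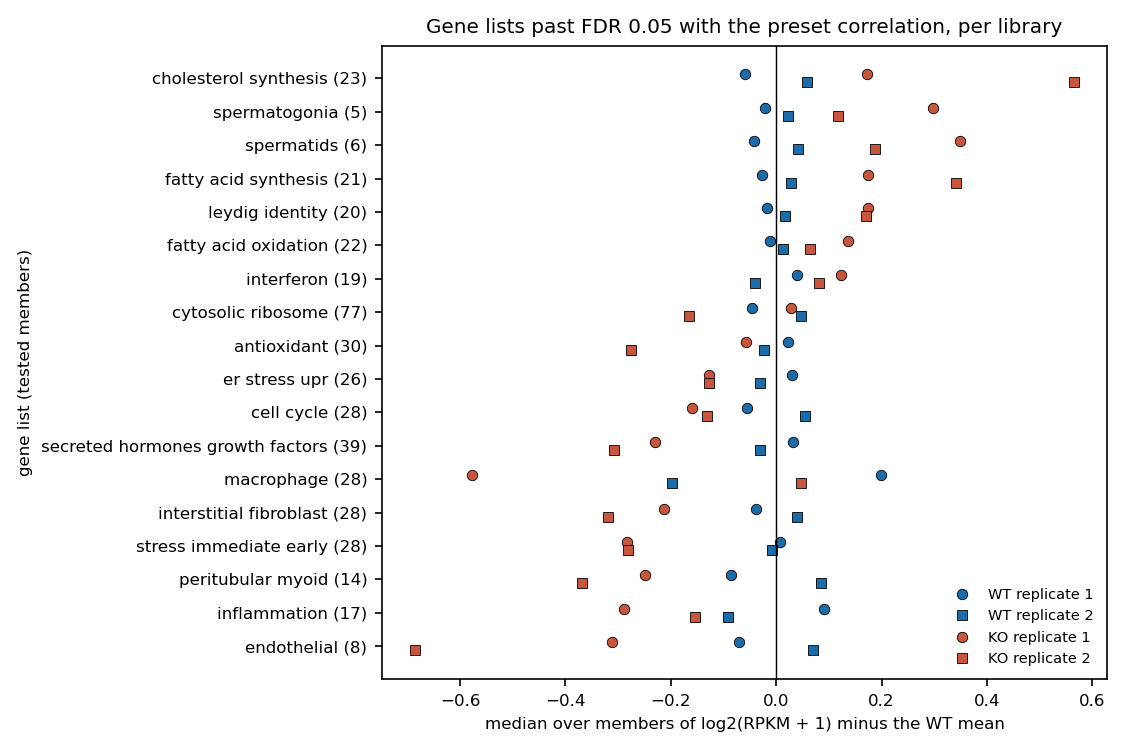
Median over the tested members of log2(RPKM + 1) minus the WT mean, on a log2 scale, for each of the 18 gene lists past an FDR of 0.05 with the preset correlation, with WT libraries in blue, KO libraries in red, circles for replicate 1, squares for replicate 2 and the number of members in parentheses. The immediate early and heat shock list lies at -0.28 in both KO libraries, and the macrophage list at -0.58 in KO replicate 1 and 0.05 in KO replicate 2.

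Across the 29 lists tested, camera with the preset correlation of 0.01 called 7 as higher and 11 as lower in KO. With an estimated correlation 0 lists passed (smallest adjusted p = 0.43, limma), with immediate early and heat shock genes (p = 0.0233) and secreted factors (p = 0.0360) under an unadjusted p of 0.05. That test rests on the 2 residual degrees of freedom and could hardly pass any list, so a lost call does not by itself show correlated members. For immediate early and heat shock genes the estimate was -0.033, below the preset, yet the camera p rose from 1.17e-08 to 0.0233. The estimate was 0.605 for cholesterol synthesis and 0.954 for macrophage genes, far above the preset. Fry called 1 list, with 8 at an unadjusted p under 0.05.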

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

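Voom on recovered reads and the GC and length correction were chosen after the data were seen. In the main limma fit 0 genes also passed an FDR of 0.10, which was not applied to the alternatives. The smallest adjusted p was 0.0510 in voom, 0.0655 in limma without trend and 0.0848 in limma at a filter of 5 RPKM. At an FDR of 0.05 the counts of 0 higher and 0 lower genes held under quantile normalization, trimmed-mean rescaling, either filter, a pseudocount of 0.1 and limma without trend. These counts also held with the replicate block, voom and the GC and length correction. With 1 library left out they ranged from 0 to 111 higher and from 0 to 195 lower, the highest without KO replicate 1; by construction the lone KO library is then assumed to vary like the WT pair. At an unadjusted p under 0.05 (536 higher, 919 lower) there were 1054 higher without a filter and 294 at a filter of 5 RPKM, where more or fewer genes were tested, and from 272 to 802 higher and 314 to 1532 lower with 1 library left out. With 1 library left out, the call changed for Insl3 alone among the 7 steroidogenic and Leydig genes. Outside these 7, it also changed for the steroidogenic enzyme gene Hsd3b6. The targeted gene, with 4 reads in all, had a difference of -0.09 that became -0.59 at a pseudocount of 0.1 and ranged from -0.17 to 0 with 1 library left out, and most other alternatives give no value below the filter.

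Of the 18 lists called by camera 0 passed with an estimated correlation and 1 with fry. With a WT library left out 29 lists were tested, and with a KO library left out 28, since spermatogonia then had fewer than 5 tested members. These fits leave 1 library in a genotype, so their calls rest on the spread of the other pair. Under the other 13 alternatives 8 lists kept their direction and call: cholesterol synthesis, fatty acid synthesis and oxidation, myoid, fibroblast, secreted factors, unfolded protein response, and immediate early and heat shock genes. Deviations from the group mean had a correlation of -0.096 across genes between libraries sharing a label suffix. This shows no pairing across the genes as a whole but cannot exclude a shared batch acting on some of them. The replicate block moved the calls to 17 lists, without cytosolic ribosome. The cause was not tested for lists whose median relative to all genes changed sign: white adipocyte (-0.0057 without a filter and -0.072 with voom), adrenocortical (0.10 without a filter), spermatogonia (-0.0017 with voom) and cAMP signalling (0.015 at a filter of 5 RPKM). With 1 library left out the median ranged from -0.0088 to 0.056 for steroidogenesis, -0.27 to 0.038 for Sertoli, -0.58 to 0.066 for macrophage, -0.0041 to 0.084 for oxidative phosphorylation, -0.15 to 0.040 for ribosome, -0.068 to 0.014 for cAMP signalling and -0.042 to 0.0043 for lysosome genes. Cyp17a1 ranged from -0.062 to 0.55. No other of the 101 genes that the naming rule chose changed direction where it was tested. At a filter of 5 RPKM 74 of them were tested, with voom 85, without a WT library 99 and without a KO library 98.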

Other observations

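The gene list and the tests of oocyte transcripts, the comparison of macrophage with myoid genes and the splits of the libraries were chosen after the values were seen, while the tests of GC content and length and of leaving out KO replicate 2 were set before theirs. Both KO libraries held more of most of a set of transcripts best known from oocytes and eggs. Of 42 such genes matched, 36 were higher in both KO libraries than in both WT libraries, 20 reached the filter, 3 reached 1 RPKM in a WT library and 1 belongs to another list. Dppa3 had 1.46 and 0.851 RPKM in WT against 6.79 and 7.26 in KO, Tcl1 0.822 and 0.685 against 4.39 and 4.31, Oog3 0.581 and 0.203 against 3.59 and 3.28, and Bmp15 0.543 and 0.579 against 2.96 and 2.46, while Mos, Zar1 and, outside the set, the germ cell gene Ddx4 (0.503 and 0.294 against 0.296 and 0.218) were not higher. Without the zona pellucida genes the list took 409 and 383 reads in WT and 1859 and 2184 in KO, a KO to WT ratio scaled to depth of 4.27 (95% Poisson interval 3.96 to 4.61, counting error only).

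Depth does not account for this pattern. Over the whole list, zona genes included, KO replicate 1 exceeded WT replicate 2, of similar depth, by a ratio scaled to depth of 4.82 (interval 4.32 to 5.39). Zp1, Zp2 and Zp3 together did not share this rise (KO to WT ratio 0.738, interval 0.343 to 1.57). That interval lay below the 3.96 to 4.61 of the rest of the list. These zona genes lay near the floor, with 17 reads in WT and 15 in KO. RNA from growing or fully grown oocytes therefore stays open on their values alone. The first test of 1 source of RNA, at a higher share in KO than in WT, gave a KO to WT ratio that differed between genes beyond counting error (chi-square per degree of freedom 2.93), but 133 of 1000 random lists matched on reads, a reference added later, were as low (median 4.26), so it decides nothing. A second test, which replaced the first when counting error alone seemed to rule the source out, asked whether the genes kept 1 ratio between the KO libraries, and they did (0.649 over 34 genes, as low as in 0 of 1000 random lists, median 3.56). The list was chosen after the values were seen, and any genes that vary together could keep such proportions. The test thus cannot tell 1 outside source in both KO libraries from a difference between genotypes. Such a source could be eggs, embryos or another library of a shared run. Both explanations stay open and untested.

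The myoid, fibroblast and matrix, endothelial and macrophage lists were called lower in KO, although the macrophage median lay above the WT mean in KO replicate 2. The Sertoli list was not called, but only 10 of its 27 listed genes were tested, without Sox9, Amh or Fshr, so it says little about the share of Sertoli cells. Macrophage genes moved apart from myoid genes by 0.74 between the KO libraries (95% bootstrap interval over genes 0.63 to 0.88). Between the WT libraries they moved apart by -0.57 (-0.72 to -0.38). Both intervals treat genes as independent, although the estimated correlation was 0.954 for macrophage and 0.454 for myoid genes. The intervals are thus too narrow and do not measure variation between pairs of libraries. By these medians macrophage and myoid genes moved separately between libraries of the same genotype. This does not test whether all other cells had a lower share in KO than in WT. Whether a lower share in the KO preparations adds to this variation stays open, since the KO gap is of the size seen within WT. GC content and length are argued against for the fibroblast and matrix list, which kept a median of -0.18 relative to all genes and its call after the correction. Different shares of single cell types, for which the labels name no sort or marker, or a difference between genotypes within these cells stay open.

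Cholesterol synthesis genes were higher in KO. Without KO replicate 2 the list had a median of 0.19 relative to all genes. Against the WT mean its median was 0.17 in KO replicate 1 and 0.57 in KO replicate 2. The WT libraries lay at -0.06 and 0.06. The direction thus does not come from KO replicate 2 alone, although most of the size does. With 1 KO library left, that fit cannot tell a shift of this size from variation between libraries. After the GC and length correction the median was 0.37, which argues against these trends as the whole cause. The list was also called when WT replicate 1 and KO replicate 1 were set against WT replicate 2 and KO replicate 2, which is the split by label suffix. The antioxidant and the insulin and glucose lists were called there too, and the macrophage and ribosome lists were called in the third split. These lists thus vary between libraries of 1 genotype, and a batch shared by suffix stays open. Different shares of cell types and a difference between genotypes are open hypotheses.

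The 4 libraries can be split into groups of 2 in 3 ways, too few for a share under 0.05. The split by genotype was the 1 split with as many genes at an unadjusted p under 0.05 (1455, against at most 527 in the others) and the 1 split with as many lists past an FDR of 0.05 (18, against at most 3).

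A few transcripts were seen almost only in WT libraries, as chosen after their values were seen. The imprinted RNA H19 had 2.62 and 2.08 RPKM in WT, and 0.0806 and 0 in KO. The cartilage collagen Col2a1 had 0.253 and 0.432 RPKM in WT and 0 and 0.0169 in KO, and Col9a2 had 0.233 and 0.368 RPKM in WT and was listed at 0 in both KO libraries.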
